A study of Mus musculus with 2 samples.

How the data were processed

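MicroRNA sequencing (microRNA-seq, in which adapters are ligated to small RNAs and the products are sequenced) was carried out on total RNA from the hindbrain of newborn mice of strain B6NCrl, at postnatal day 0. The series holds 1 group of 2 libraries, each from the single hindbrain of a different pup, called pup 1 and pup 3 per the labels. The labelled size range of the RNA was below 30 nt. The sex of the pups was not collected, per the labels.

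For each library the authors deposited a table of raw read counts for 1973 microRNA genes, aligned to mouse assembly mm10 and annotated with GENCODE release M4, per the listings deposited with the tables. The aligner, its version and the trimming of adapters are not given in the sources used here. Each table has 3 columns of counts per gene, and 4 further rows for reads that were unmapped, mapped to several loci, fell outside genes or were ambiguous. No source used here describes the columns. Their layout is that of a counter that assigns only reads mapped to a single locus, and the meaning of columns and rows was inferred from it. The first column equals the sum of the other columns for every gene, and the column that holds nearly all counts of abundant genes was taken as the count of reads on the strand of the gene. That same-strand column was used throughout, and the opposite-strand column only where it is named. The 4 rows that name no gene were left out of library totals. In pup 1 unmapped reads were 13.7%, multimapped reads 40.2% and reads with no listed microRNA gene on their strand 3.79% of all reads. In pup 3 these shares were 12.4%, 42.0% and 3.63%. The last share was taken from the same-strand column, so by the inferred layout it includes reads on the opposite strand of a gene. Because a read that maps to several loci is not counted, a gene whose mature microRNA is encoded at more than 1 locus can be undercounted in these tables.

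Counts are per precursor gene, so the 5′ and 3′ arms of a precursor cannot be told apart. Gene symbols, coordinates and host genes were taken from GENCODE M21, which uses the same assembly (GRCm38, mm10). By Ensembl identifier without its version, 1894 of the 1973 rows matched, and 79 did not. Of those 79, 2 had any count, and they were kept under their identifiers. Precursor sequences of the same release gave GC content and the number of other loci that share an identical stretch of 20 nt with a precursor on either strand, overlapping genes excluded.

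The 2 libraries held 5812558 and 7175976 reads, of which 2459757 and 3012320 were counted on the strand of a microRNA gene. CPM (counts scaled to the library's total) were computed over these totals, and shares are percent of them. Values are given as mean ± SD over the 2 pups (n = 2). A count of 0 allows up to 3 counts, or 1.22 CPM in pup 1 and 0.996 CPM in pup 3. Intervals marked exact are 95% Clopper-Pearson binomial intervals. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

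With 1 group, no condition was compared. The design implies the profile of the tissue and the comparison of its replicates. Agreement was described by Pearson's r and Spearman's rho of log2(CPM + 1) across genes with at least 10 counts in either library, with bootstrap intervals over genes (1000 draws). The spread between the pups was estimated as the common biological coefficient of variation (edgeR 4.0.16 in R 4.3.3, intercept-only design, TMM factors, genes with at least 10 counts in both libraries, 100 bootstrap draws). Each gene's 2 counts were compared with an exact binomial test given the TMM-scaled totals, two-sided, with Benjamini-Hochberg adjustment at 0.05 (scipy 1.17.1). This test compares the 2 libraries beyond counting error and says nothing of a condition. Folds are pup 3 over pup 1 with a prior of 0.5 counts. edgeR's quasi-likelihood test needs replicates on each side and was not run.

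For this comparison, data were simulated with counting error alone and no spread between pups, and 392 genes were tested. The binomial test called 85 of 98 genes changed 2-fold, 67 of 97 genes changed 1.5-fold and 5 of 197 unchanged genes. These rates do not cover the spread between pups that the real data hold. A simulated coefficient of variation of 20% was estimated as 18.7% over 360 genes. The permutation test of folds within groups of genes passed its threshold in 2 of 100 simulated data sets with no group effect and in 100 of 100 with one. The simulated groups were of equal size and differed in number and size from the groups tested here.

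Before the data were examined, 21 lists of microRNA genes were fixed: neuronal, neural progenitor, the Mir17-92 cluster with its paralogs, oligodendrocyte, leukocyte and microglia, red blood cell, endothelial, smooth muscle, striated muscle, liver, epithelial, choroid plexus, multiciliated cell, sensory organ, endocrine, Hox-encoded, let-7, Mir99/100 with Mir125, the imprinted Dlk1-Dio3 region, pluripotent cell and an X-linked germline cluster. Also fixed were the rule for named genes and the alternatives. Named genes are the 20 with the highest mean CPM, up to 4 members of each list with the highest mean CPM, and, among genes with at least 100 CPM in both libraries, the 5 with the largest fold in each direction. Other genes are named with the statement that they were chosen after their values were seen. Alternatives were the column of counts on either strand, DESeq2 1.42.0 size factors or plain totals in place of TMM, no filter or at least 100 counts in both libraries, leaving out the most abundant gene, leaving out genes whose symbol ends in a copy number, and each library alone. Beside counts of list members that differed, the counts adjusted over the list alone are given where these are not the same. A GC correction and the addition of opposite-strand counts were added after seeing the data.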

Results

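MicroRNA counts were obtained from the hindbrains of 2 newborn mice, and the question the data address is which microRNA genes this tissue contained at birth and how closely 2 pups agreed. Pup 1 gave 2459757 and pup 3 gave 3012320 counts on the strand of a microRNA gene. Of 1973 genes in the tables, 699 had at least 1 count in either library and 1274 had none. These counts leave out reads that map to several loci, 40.2% of all reads in pup 1 and 42.0% in pup 3. Of 1894 genes with a precursor sequence, 929 share 20 nt with another locus and can be undercounted. A gene with no count is therefore not shown to be absent. Both libraries reached 10 CPM for 306 genes. The 10 most abundant genes held 48.5% ± 1.05 (SD, n = 2) of the counts.

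Among reads mapped to a single locus, the most abundant gene was Mir99a (ENSMUSG00000065530.1), at 16.5% ± 1.31 of counts (SD, n = 2, as for all following values given with ±). Mir99a lies in an intron of Mir99ahg on chromosome 16 (77598936 to 77599000, mm10), and its CPM was more than that of any other gene in both pups. Mirlet7g, in an intron of Wdr82 on chromosome 9, followed at 7.22% ± 0.952. Mir487b of the imprinted Dlk1-Dio3 region on chromosome 12 held 5.11% ± 0.191, and it shares 20 nt with 1 other locus. Mir126a, an endothelial microRNA in an exon of Egfl7 on chromosome 2 (26591357 to 26591429), held 3.56% ± 0.192. Mir335, in an intron of the imprinted gene Mest on chromosome 6, held 3.28% ± 0.163. Mir10a (chromosome 11, 96317165 to 96317274) and Mir10b (chromosome 2, 74726070 to 74726137, in introns of Hoxd3 and Hoxd4), encoded in the Hox clusters, held 2.96% ± 0.861 and 1.55% ± 0.754. The rest of the 20 most abundant genes were Mir100, Mirlet7i, Mir130a, Mir30e, Mir26b, Mir149, Mir99b, Mir127, Mir181c, Mir137, Mirlet7b, Mirlet7d and Mir22, each between 1.08% and 2.74% of counts.

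The families of Mir99/100 and Mir125 and of let-7 held large shares of the counts. All 6 measured members of the Mir99/100 and Mir125 list were detected at 10 CPM, with 21.7% ± 1.52 of counts. All 10 measured let-7 genes were detected, with 12.998% ± 1.62. Mirlet7i reached 26868 ± 3333 CPM, Mirlet7b 11735 ± 580 CPM and Mirlet7d 11049 ± 1984 CPM. The 5 let-7 genes that share 20 nt with other loci had lower counts than these. Among them, and chosen after their values were seen, Mirlet7c-1 had 441 ± 9.64 CPM and Mirlet7a-1 had 223 ± 14.8 CPM.

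The Dlk1-Dio3 region, an imprinted domain whose microRNAs are read from the maternal chromosome, was broadly represented. Of 50 measured list members, 42 were detected and 4 had no count, and together they held 13.98% ± 0.256 of counts. Those with counts lie between positions 109563692 and 109747960 of chromosome 12. After Mir487b came Mir127 at 13860 ± 127 CPM, Mir382 at 10017 ± 1236 CPM and Mir369 at 9984 ± 29.5 CPM, the latter pair within exons of Mirg.

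Neuronal microRNAs held 5.01% ± 0.0675 of counts, and 20 of 23 measured members were detected. Mir149, in an intron of Gpc1, had 16538 ± 1327 CPM. Mir137, which acts in neuronal differentiation, had 12408 ± 1160 CPM, Mir128-1 had 5957 ± 941 CPM and Mir153 had 2752 ± 1042 CPM. The 3 genes for miR-124, a microRNA known for its abundance in neurons, had few counts, and are named here after their values were seen. Mir124a-1 had 12 and 17 counts, Mir124a-2 had 4 and 9, and Mir124a-3 had 3 and 2 in pups 1 and 3. Among neural progenitor microRNAs, which held 0.323% ± 0.0189, Mir92b had 2749 ± 125.1 CPM and Mir9-3 had 478 ± 64.7 CPM, while Mir9-2 had 3 and 5 counts. Each of these Mir124a and Mir9 genes shares 20 nt with 2 or 3 other annotated microRNA genes, and reads that map to several loci are not in these counts.

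The neuronal, neural progenitor, let-7, and Mir99/100 and Mir125 lists, chosen after the values were seen, hold 22 genes that share 20 nt with another locus, with a median of 394 CPM, and 20 that do not, with a median of 4652 CPM. Without the 5 Mir124a and Mir9 genes, whose low counts prompted the comparison, the other 17 sharing genes had a median of 714 CPM, and the difference of medians was -2.69 on the log2(CPM + 1) scale (two-sided permutation test, p = 0.00651, 100000 draws). The Dlk1-Dio3 list has 6 sharing genes, from Mir3070b at 1.57 CPM to Mir411 at 7129 CPM and Mir487b at 51112 CPM. Mir3070b and Mir411 are named after their values were seen. With that list added, the difference was -0.49 (p = 0.731, same permutation test), and over all 21 lists it was -0.74 (p = 0.394, same permutation test). Within the Dlk1-Dio3 list alone it was -0.72 (permutation p = 0.703), and over the 17 lists other than the first 4 it was -5.09 (permutation p = 0.00066). The sign was the same in each set, while the size depended on which lists were pooled. In the 17 lists the 29 sharing genes had a median of 2.88 CPM, and they include 5 germline and 4 striated muscle genes. The permutation did not keep genes within their lists, so its p-values cannot separate sharing from list.

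**Figure D1:**
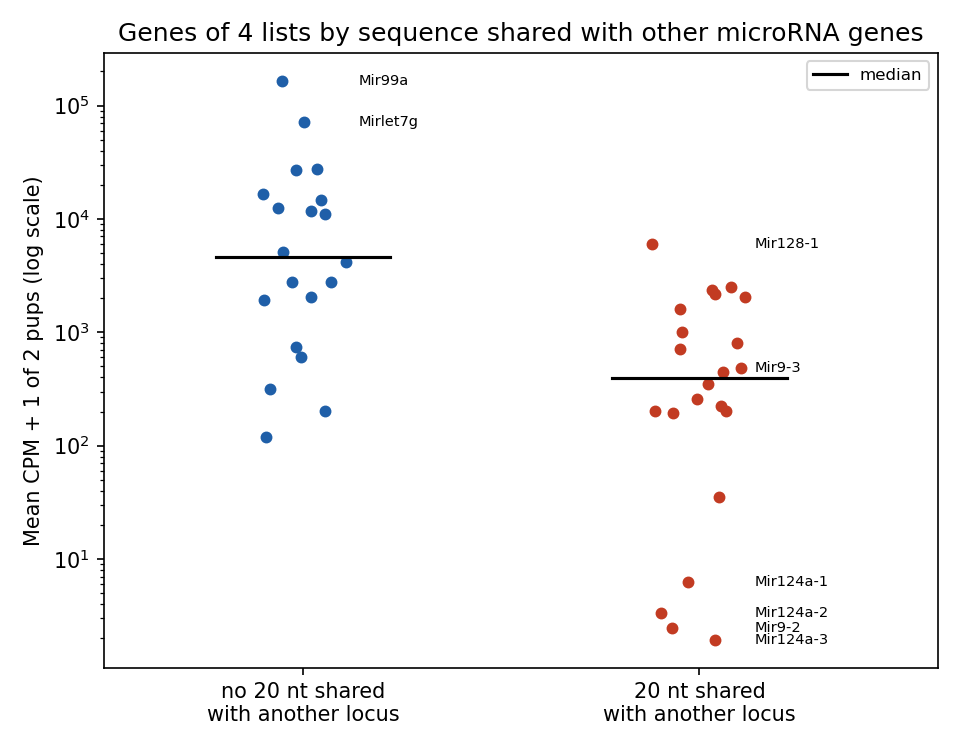
Mean CPM + 1 over 2 pups (log axis) of the 42 genes of 4 lists, each point a gene, split by whether the precursor shares 20 nt with another microRNA locus; bars are medians. The genes without sharing have a median of 4652 CPM and those with sharing 394 CPM, and the Mir124a genes and Mir9-2 lie lowest.

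MicroRNAs of other cell types and of position along the body axis were also present. The Hox-encoded list held 4.57% ± 1.62, nearly all from Mir10a and Mir10b. Mir615, in an intron of Hoxc5, had 528 ± 5.36 CPM, and Mir196b, in an exon of Hoxa9, had 15.7 ± 2.50 CPM. The clusters of Mir17-92 and its paralogs, known from proliferating cells, held 3.19% ± 0.108 with 13 of 15 members detected, led by Mir17 at 10724 ± 1354 CPM and Mir106b at 6218 ± 757 CPM. Oligodendrocyte microRNAs held 0.181% ± 0.0265, with Mir219a-2 at 939 ± 156 CPM and Mir338 at 758 ± 110 CPM. Choroid plexus and multiciliated cell lists held 0.409% ± 0.0755 and 0.926% ± 0.00751. Their leading members were Mir204, in an intron of Trpm3, at 4082 ± 752 CPM, Mir449a, in an intron of Cdc20b, at 5231 ± 328 CPM and Mir34c at 3884 ± 251 CPM.

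Vessel and blood lists ranged widely. Besides Mir126a, smooth muscle microRNAs held 0.867% ± 0.148, nearly all of it Mir143 at 8471 ± 1483 CPM, while Mir145a had 203 ± 5.01 CPM. Leukocyte and microglia microRNAs held 0.0651% ± 0.00503, with Mir223 at 199 ± 42.6 CPM. Mir142, named after its values were seen, has no row of its own and is left out of that share. Opposite-strand reads at Mir142b, where Mir142 lies, came to 316 ± 106 CPM, more than Mir223 had. With opposite-strand counts added, also chosen after seeing the data, the list held 0.0938%. Red blood cell microRNAs held 0.0144% ± 0.00289. The sensory organ list (Mir96, Mir182 and Mir183) held 0.241% ± 0.0538, the epithelial list 0.0788% ± 0.0105, led by Mir203 at 607 ± 72.6 CPM, and Mir375, of endocrine cells, 0.0512% ± 0.00243.

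Lists of other tissues and stages had low shares. In them, 4 of 8 striated muscle, 4 of 12 pluripotent cell and 5 of 16 germline members share 20 nt with another locus, so these lists can be undercounted. Striated muscle microRNAs held 0.0133% ± 0.00218, of which Mir206 had 112 ± 18.7 CPM. Pluripotent cell microRNAs held 0.0375% ± 0.00452, with Mir302d at 131 ± 1.67 CPM and 3 of 12 members at no count. The liver microRNA Mir122 held 0.00419% of counts in pup 1 (exact interval 0.00342% to 0.00508%) and 0.00455% in pup 3 (0.00382% to 0.00538%). The X-linked germline cluster had 12 counts in pup 1, or 0.000488% (exact interval 0.000252% to 0.000852%), and 20 in pup 3, or 0.000664% (0.000406% to 0.00103%), and 10 of its 16 members had none.

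**Figure D2:**
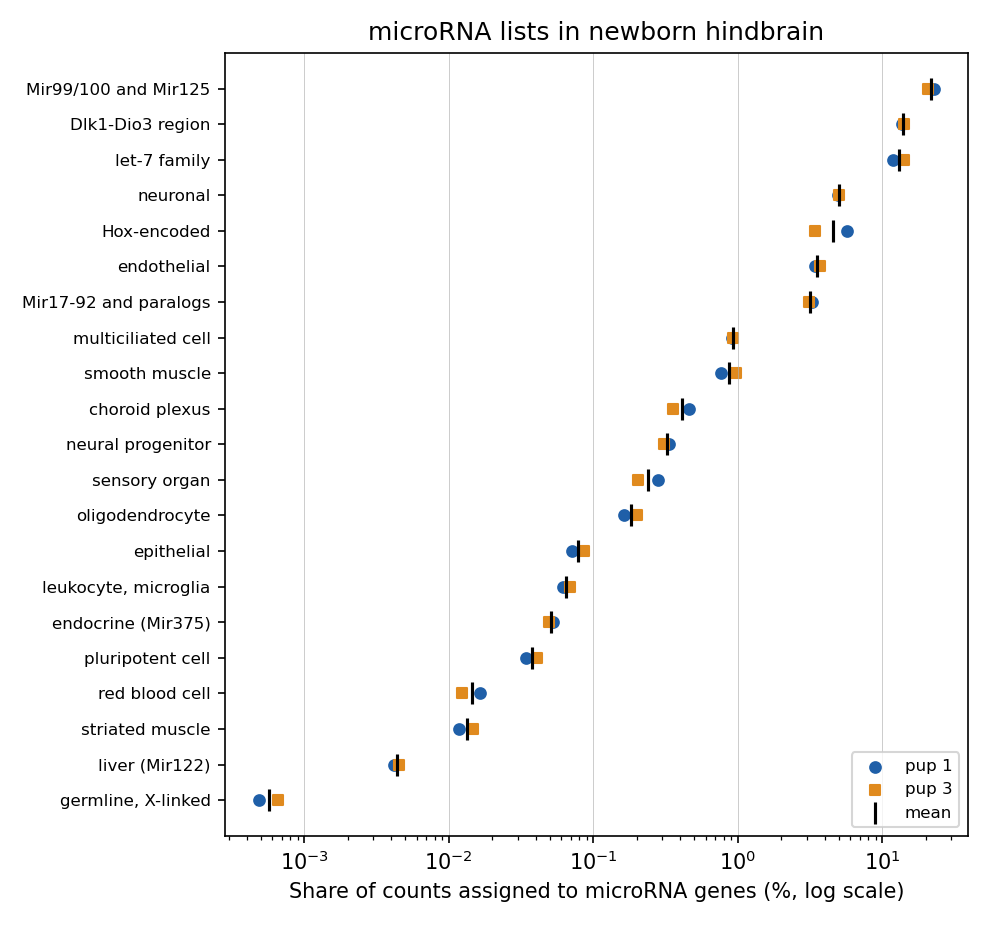
Share of counts assigned to microRNA genes (percent, log axis) for 21 lists, with pup 1 as circles, pup 3 as squares and their mean as a bar. Shares run from 21.7% for Mir99/100 and Mir125 to 0.000576% for the germline cluster, and the Hox-encoded list was 5.71% in pup 1 and 3.43% in pup 3.

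The 2 pups agreed closely in rank and level. Across 395 genes with at least 10 counts in either library, Pearson's r of log2(CPM + 1) was 0.993 (bootstrap interval 0.991 to 0.994) and Spearman's rho 0.990, where genes are not independent replicates. The common biological coefficient of variation was 16.6% (bootstrap interval 14.4% to 18.2%, 361 genes), which corresponds to an SD of 0.34 for a log2 fold between 2 pups. Of 226 genes with at least 100 CPM in both libraries, 224 lay within 2-fold of each other. The libraries were not one library counted again, since their counts differed beyond sampling (chi-square 49286 on 394 degrees of freedom).

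Differences beyond counting error were also frequent. By the exact binomial test with Benjamini-Hochberg adjustment, 185 of 395 genes differed, 101 higher and 84 lower in pup 3, and 38 of them by over 1.5-fold. This counts genes that differ between these libraries, with no replicate on either side. Among the 226 genes with at least 100 CPM in both libraries, the 5 lowest in pup 3 relative to pup 1 were Mir181b-2 (log2 fold -1.14), Mir10b (-1.09), Mir182 (-0.93), Mir138-1 (-0.85) and Mir129-1 (-0.79). The 5 highest among these 226 were Mir32 (0.80), Mir153 (0.74), Mir101a (0.62), Mir374b (0.62) and Mir3071 (0.61). Of these, Mir181b-2, Mir138-1, Mir129-1 and Mir101a share 20 nt with at least 1 other locus.

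Of the 21 lists, the Hox-encoded microRNAs had the largest difference of summed counts between the pups, with a log2 fold of -0.79. Mir10a had 35717 CPM in pup 1 and 23544 CPM in pup 3 (log2 fold -0.65, counting interval -0.67 to -0.64), and Mir10b had 20858 and 10196 CPM (log2 fold -1.09, interval -1.11 to -1.07). Mir615 and Mir196b did not pass the test (log2 folds -0.07 and -0.38). In the let-7 list, 5 of 10 genes were higher in pup 3, 1 was lower and 4 did not pass (6 higher and 2 lower adjusted over the list alone). In the Dlk1-Dio3 list, 14 of 44 tested genes were higher, 8 lower and 22 did not pass, with equal counts adjusted over the list alone. In the neuronal list, 7 of 21 were higher, 8 lower and 6 did not pass, with equal counts adjusted over the list alone. The red blood cell microRNAs Mir451a and Mir144, neighbours on chromosome 11 (78073170 to 78073241 and 78073005 to 78073070), differed in opposite directions. Mir451a had 329 counts in pup 1 and 113 in pup 3 (log2 fold -1.88, interval -2.21 to -1.57), and Mir144 had 42 and 202 (log2 fold 1.91, interval 1.44 to 2.44).

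**Figure D3:**
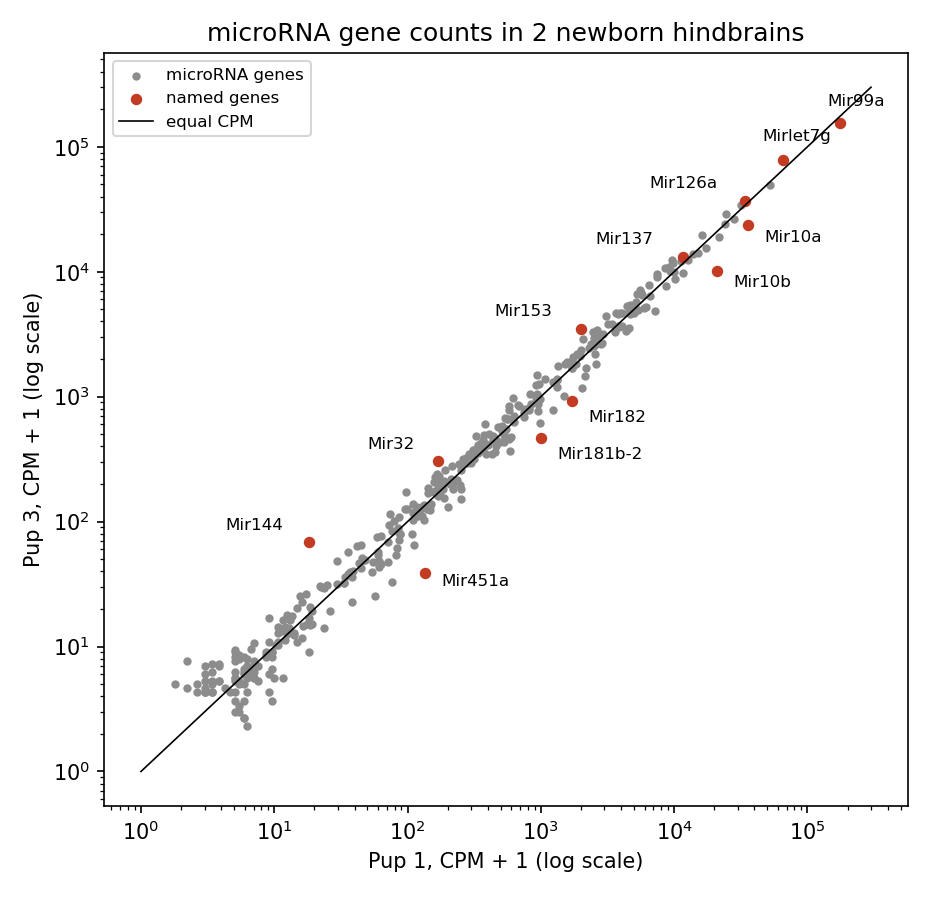
CPM + 1 in pup 1 (horizontal) against pup 3 (vertical), both on log axes, for 395 microRNA genes with at least 10 counts in either library; the line marks equal CPM and labelled red points are some of the named genes. Most genes follow the line, while Mir10a, Mir10b, Mir182, Mir181b-2 and Mir451a lie below it and Mir144, Mir153 and Mir32 above it.

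The opposite-strand column held 2.69% and 3.22% of the either-strand counts of pups 1 and 3. At 11 genes opposite-strand counts exceeded same-strand counts in both libraries, and these genes made up 99.9% of the opposite-strand counts. At each of the 11, GENCODE M21 annotates a microRNA gene on the other strand that has no row in the tables used here. The 20 most abundant genes together had 20 opposite-strand against 3396819 same-strand counts.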

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

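The tests of explanations in this part were chosen after the results were seen. Reads in the opposite-strand column, which no comparison above uses, exceeded both the same-strand counts and the 3 counts that a count of 0 allows in each library at 11 genes. Summed over both pups they numbered 45991 at Gm25252 (opposite Mir376a), 29727 at Gm25927 (opposite Mirlet7e), 24919 at Gm24321 (opposite Mir409), 24741 at Gm24083 (opposite Mir191) and 18056 at Gm25301 (opposite Mir378a). They numbered 10978 at Gm25750 (opposite Mir380), 7351 at Mir497b (opposite Mir497), 3389 at Mir299b (opposite Mir299a), 1770 at Mir142b (opposite Mir142), 643 at Gm24111 (opposite Mirlet7f-1) and 524 at Gm25641 (opposite Mir9-1). In CPM of the same-strand totals, the reads opposite Gm25252 came to 8217 ± 2626 and those opposite Gm25927 to 5387 ± 631 (SD, n = 2).

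Reads that map to several loci, also unused, made up 41.1% ± 1.29 (SD, n = 2) of all reads. The 3 Mir124a genes and Mir9-2 had at most 17 counts in either library although miR-124 and miR-9 are known as abundant in brain. A candidate explanation is that their reads are among those that map to several loci, which would lower other genes that share 20 nt with another locus too. The Mir124a and Mir9 genes left out, such genes had a lower median in 4 lists (difference -2.69 on the log2(CPM + 1) scale, two-sided permutation p = 0.00651). Over all 21 lists the difference was -0.74 (p = 0.394, same permutation test), and over the 17 lists other than those 4 it was -5.09 (permutation p = 0.00066). The sign is the same in each set, but the permutation did not keep genes within their lists. It therefore cannot separate sharing from list, so the explanation stays open. That these microRNAs were scarce in newborn hindbrain cannot be told apart from this, since 41.1% of reads have no gene and could hold them.

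The 185 genes that differed between the pups may reflect library preparation as well as biology. A linear correction for precursor GC content left 158 of the 185 called. In all, 180 of 395 genes were called after it, so some calls were new. The linear fit on GC content held 2.79% of the variance of the folds. These values argue against a linear effect of precursor GC content as the whole cause. The GC content of the sequenced small RNAs themselves was not tested. Copies of 1 microRNA, all 11 pairs on different chromosomes, had folds close to each other (pooled SD 0.12, bootstrap interval 0.07 to 0.16, one-sided permutation p = 0.00078, against 0.32 for random genes), as in Mir138-1 and Mir138-2 (-0.85 and -0.72) or Mir16-1 and Mir16-2 (-0.58 and -0.72). Neighbours within 10 kb on 1 strand were 119 genes in 36 clusters. Their folds were less close than those of the copies (SD 0.29, interval 0.24 to 0.35, one-sided permutation p = 0.061). That SD holds counting error, and some neighbours are copies, as Mir16-2 (-0.72) beside Mir15b (0.33). Of neighbours that share no 20 nt with another locus, some had like folds, as Mir99b (-0.16) and Mir125a (-0.19). Others differed beyond counting error, as Mir17 (-0.31, interval -0.33 to -0.29) and Mir18 (0.18, interval 0.13 to 0.23). Pairs of the latter kind argue against transcription of the shared precursor as the whole cause of their folds. Reads that map to both copies of a pair are not counted, and which other reads were counted at each copy is not known. The likeness of copies therefore cannot be tied to the mature sequence. Recovery that depends on the mature sequence and turnover of the mature RNA both stay open, and the comparison of copies cannot decide between them.

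Mir10a and Mir10b were both lower in pup 3, by 1.93 and 3.20 times the SD of folds that the coefficient of variation gives, so that Mir10a alone lies under 2 such SDs. The highest of their log2 folds under 3 scalings was -0.60, so the choice among these scalings does not account for the lower values. A scaling moves every fold by the same amount, and TMM moved them by -0.053 relative to plain totals. Folds of this size could hardly change sign, so the comparison is a weak test of scaling as a cause. Less caudal tissue in the piece taken from pup 3 is a hypothesis that would lower other Hox-encoded microRNAs too. Mir615 had a log2 fold of -0.074 (interval -0.18 to 0.03, and 0.092 after the GC correction) and Mir196b one of -0.38 (interval -1.03 to 0.27). The interval of Mir615 lies above the folds of Mir10a and Mir10b, so Mir615 showed no fall of that size. The interval of Mir196b includes both 0 and a fold as low as that of Mir10a. Both intervals cover counting error only and not the spread between pups. Less caudal tissue therefore cannot be told apart from a difference in Mir10a and Mir10b alone.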

How the results depend on the processing

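No paired analysis was possible because the series holds 1 group. Pearson's r ranged from 0.991 to 0.993, the coefficient of variation from 0.158 to 0.168, the number of detected genes from 273 to 315 (309 in each pup alone) and the number of differing genes from 171 to 196 over the alternatives run for each, the GC correction added later included. The share of tested genes that differed went from 46.8% to 25.3% without a filter (177 genes) and to 68.7% with at least 100 counts in both libraries (180 genes), as the number of genes tested changed. With at least 100 counts in both libraries, 23 genes in place of 38 differed by over 1.5-fold. Under plain totals 115 genes were higher and 76 lower in pup 3. Without a filter on low counts Spearman's rho was 0.943. Leaving out 1 of 2 pups leaves the other's share, which lies within 1 SD of the mean by construction. Shares are relative to the total, so leaving out Mir99a, the most abundant gene, moved many: the 10 most abundant genes to 40.5%, Mir99/100 and Mir125 to 6.202%, Dlk1-Dio3 to 16.7%, let-7 to 15.6%, neuronal to 5.999%, endothelial to 4.26%, Mir17-92 to 3.82%, multiciliated to 1.11%, smooth muscle to 1.04%, choroid plexus to 0.491%, neural progenitor to 0.387%, oligodendrocyte to 0.217%, epithelial to 0.0943%, leukocyte to 0.0779%, endocrine to 0.0614%, pluripotent to 0.0448%, striated muscle to 0.0159% and liver to 0.00523%. Leaving out copy-numbered genes gave 50.1% for the top 10, 3.89% neuronal, 0.284% neural progenitor, 0.0783% oligodendrocyte, 0.957% multiciliated and 14.5% Dlk1-Dio3. The either-strand column gave 47.0% for the top 10, 4.86% neuronal, 0.0938% leukocyte, 0.898% multiciliated and 13.6% Dlk1-Dio3. Adding opposite-strand counts under the unlisted genes, chosen after seeing the data, gave 4.86% neuronal, 0.0938% leukocyte, 0.898% multiciliated and 15.1% Dlk1-Dio3. Among named genes whose fold passed the threshold, 4 small folds changed sign: under plain totals Mir130a (0.000696) and Mir369 (0.00602), and under the GC correction, also chosen afterwards, Mir335 (-0.0221) and Mir92b (0.00147). These sign changes follow from the adjustments themselves. TMM moved every fold by -0.053 on the log2 scale relative to plain totals, and the GC correction subtracted a fitted trend at each gene's GC content. Folds of 8 further named genes that did not pass the threshold changed sign under at least 1 alternative and stayed short of it, among them Mir615 (0.092 under the GC correction). Of the 4 genes whose fold had passed the threshold and changed sign, only Mir335 stayed past it. Under at least 1 alternative, 7 other named genes kept their sign but were no longer past the threshold (Mir126a, Mir99b, Mir127, Mir155, Mir206, Mir429 and Mir375). Mir150 passed it under 3. Without a filter, Mir206 and Mir429 lost the call at the same fold (0.29 and 0.33), since more genes were tested. At this depth a count of 0 allows up to 1.22 CPM in pup 1, and 2 libraries give no error for the difference of a single gene between the pups beyond counting.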

Other observations

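Further groups of microRNAs were picked out after their values were seen. The 6 genes with a mean of at least 1 CPM in introns of Htr2c on the X chromosome, the gene of a serotonin receptor known from choroid plexus, held 0.810% ± 0.00231 of counts (SD, n = 2). Mir1298 led them at 6496 ± 129 CPM, followed by Mir448 at 942 ± 37.1 CPM, Mir1264 at 617 ± 67.7 CPM, Mir764 at 21.7 ± 4.91 CPM and Mir1912 at 20.9 ± 6.58 CPM. The 12 genes with a mean of at least 1 CPM in introns of Sfmbt2 on chromosome 2 held 0.466% ± 0.0212, with Mir467e at 1686 ± 220 CPM and Mir467d at 1275 ± 47.7 CPM. By chromosome, the largest shares came from chromosome 16 at 17.5% ± 1.34, chromosome 12 at 15.1% ± 0.239 and chromosome 9 at 11.1% ± 0.752. The X chromosome held 4.19% ± 0.409 of counts and 38 of its 120 genes were detected.

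Several neighbouring genes differed between the pups by unlike amounts. Mir182 had a log2 fold of -0.93, against -0.05 for Mir183 and 0.02 for Mir96 on the same strand of chromosome 6. Mir181b-2 had -1.14, against -0.17 for Mir181a-2. Mir451a and Mir144 differed at -1.88 and 1.91, or 5.55 and 5.62 times the SD of folds that the coefficient of variation gives, which leaves out counting error (Mir144 had 42 counts in pup 1).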
